A study of Homo sapiens with 6 samples.

How the data were processed

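RNA was measured by sequencing in 6 libraries of leukemic pre-B cells, 3 from pS6-positive patients who later relapsed and 3 from pS6-negative patients who stayed in remission. Per the labels, the cells were sorted by flow cytometry from thawed diagnostic bone marrow by low CD45 and the presence of CD10, CD34 and CD38, with CD43, CD24 and CD19 at high levels. RNA was prepared with a kit for small samples, and libraries were made with SMARTer Ultra Low chemistry, which primes on poly(A) tails and amplifies by PCR. The authors deposited a table of raw counts, reads per Ensembl gene with no normalization, with 1 column per library. Their processing notes name the GRCh38 genome and DESeq2, without saying what DESeq2 was used for. The aligner, the counting program and the annotation release were not given in the sources used here.

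The deposited table held 58053 rows. A total of 3 gene IDs stood on 4 identical rows each and were kept once, which left 58044 gene IDs, all of them in GENCODE release 29, from which positions were taken. Because the cells came from donors, 1204 sex-linked, immune receptor segment and genotype-dependent genes were left out before any fit, and 56840 genes were kept. These genes took 1.26% to 1.85% of the counts of a library. Total counts ran from 5735217 to 19217928 per library. Reads carried no molecular identifiers and were amplified by PCR, so counts are not independent molecules.

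Counts were compared between the groups with edgeR 4.0.16 in R 4.3.3, using TMM normalization and filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 21575 genes. The test was edgeR's quasi-likelihood test with robust estimation and a model of group alone. Benjamini-Hochberg adjustment ran over all tested genes at a threshold of 0.05. Levels are CPM, read counts scaled to library size with TMM factors, given as the group mean ± SD over 3 libraries. Log2 fold changes are pS6-positive relapse over pS6-negative non-relapse. Their SE is an approximation, the absolute log2 fold change divided by the square root of the test's F statistic. The p-values compare separate donors. An exact two-sided permutation test of 3 against 3 libraries cannot give a p under 0.1. Simulated counts followed the trend of dispersion with level in these libraries, drawn independently for each gene and without uneven background. Groups of 50 genes with a mean of at least 5 CPM were changed. The test recovered 2% of genes at a log2 change of 1, 28% at 2, 70% at 3 and 98% at 5. Of unchanged genes, 4.28% had an unadjusted p under 0.05.

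Before the data were examined, 43 gene lists were fixed, with 776 entries of which 774 matched a gene ID. They covered nucleotide, energy and lipid metabolism, mTORC1 and translation, proliferation, stress, B cell signalling and development, apoptosis, and markers of other marrow cells. Lists were tested with camera in limma 3.58.1 on the edgeR fit, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with the correlation estimated from the data, and fry, were run beside it. The genes to name were also set by a rule fixed in advance. It took the de novo pyrimidine list, then in each direction the 12 genes of smallest p with an absolute log2 fold change of at least 1, a mean of at least 5 CPM and no overlap between the groups. It also took up to 3 members of smallest p from each list described. Which of the lists outside the called ones were described by their members was decided after the values were seen. For each library, 578 genes that blood cells hardly use (olfactory and taste receptors, keratin-associated, late cornified envelope, beta-defensin and PRAME family genes) served as a measure of background, a choice also made after the data were seen.

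The separation of the libraries by group was the mean Euclidean distance between groups minus that within groups, on log2 CPM with a prior count of 2 over the 500 most variable genes, with an exact permutation test over 10 splits. The alternatives chosen in advance were RLE and upper-quartile factors, total library size, no filter on low counts, a stricter filter at a mean of 5 CPM, DESeq2 1.42.0, limma voom with and without sample weights, no robust estimation, the replicate number as a block, the left-out genes kept, library sizes without mitochondrial, ribosomal protein and haemoglobin genes, and each library left out in turn. Those added after seeing the data were the background level as a covariate, counts with the background subtracted by exon length, both libraries of highest background left out, protein-coding genes only, and DESeq2 on the genes tested by edgeR.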

Results

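RNA was sequenced from sorted leukemic pre-B cells of patients with B-cell acute lymphoblastic leukemia, taken at diagnosis. The labels put 3 libraries in a group positive for phosphorylated ribosomal protein S6 (pS6), a readout of mTORC1 and S6 kinase activity, from patients who later relapsed. Another 3 came from pS6-negative patients who stayed in remission. Each replicate is a different patient, and pS6 status coincided with relapse, so the comparison cannot separate them. The relapse libraries held 19217928, 8169791 and 16130137 counts, and the non-relapse libraries 12550485, 18141142 and 5735217.

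Genes with at least 1 count numbered 29136, 40039 and 36454 in the relapse libraries and 52509, 25971 and 44626 in the non-relapse libraries. In 578 genes that blood cells hardly use, such as olfactory receptors, the summed level was 951 CPM in non-relapse replicate 1 and 518 in replicate 3, against 76.6 in replicate 2. The relapse libraries stood at 76.3, 273 and 116 CPM. This background therefore was highest in libraries of the non-relapse group. TMM factors were also highest there, at 1.36 in non-relapse replicate 1 and 1.16 in replicate 3. They were 0.87 in non-relapse replicate 2 and 0.83, 1.03 and 0.85 in the relapse libraries. Haemoglobin genes took at most 0.003% of the counts of any library.

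**Figure D1:**
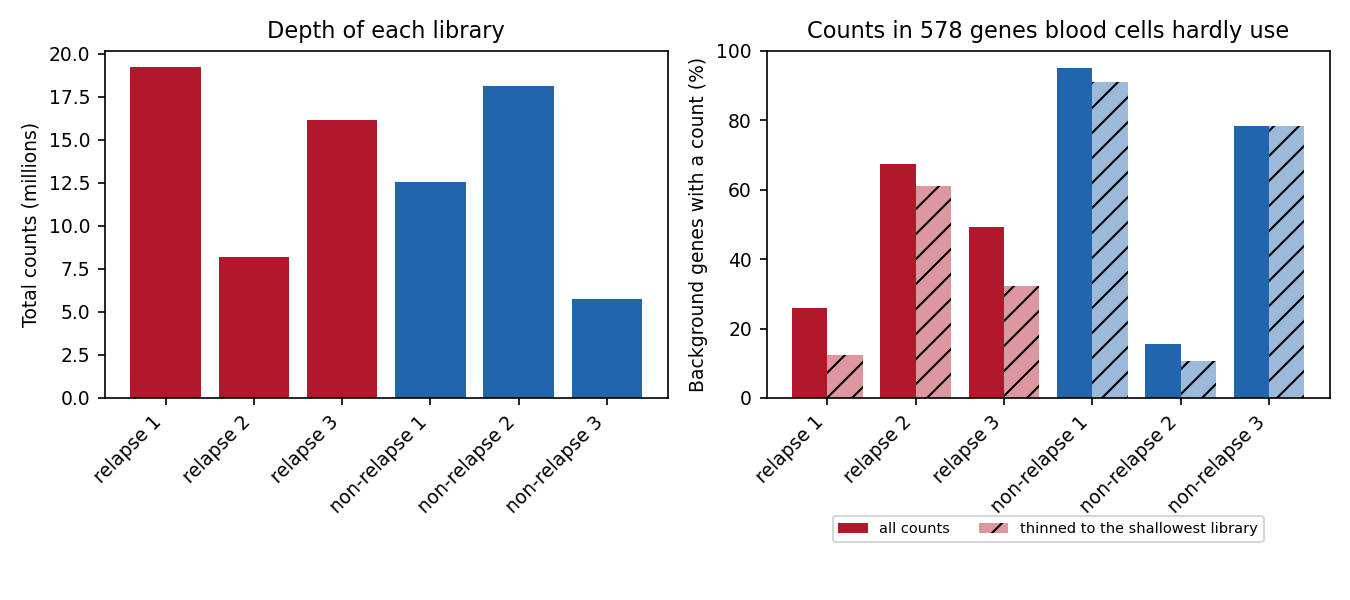
The left bars give the total counts of each library and the right bars the percentage of 578 genes that blood cells hardly use with at least 1 count, for all counts (solid) and after thinning to the shallowest library (hatched); red is pS6-positive relapse, blue pS6-negative non-relapse. After thinning the share ran from 10.7% in non-relapse replicate 2 to 91.0% in non-relapse replicate 1.

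The series asks whether DHODH, the mitochondrial enzyme that oxidises dihydroorotate in pyrimidine synthesis, is a metabolic weak point of resistant leukemia. DHODH (ENSG00000102967, GRCh38 chromosome 16, positions 72008588 to 72027664) stood at 19.6 ± 6.82 CPM (SD, n = 3) in the relapse group and 12.5 ± 3.00 CPM in the non-relapse group, with overlapping libraries. Its log2 fold change was 0.65 ± 0.41 (SE). The enzymes on either side of it lay the same way. CAD, which carries out the opening steps of the pathway, stood at 112 ± 29.8 against 72.4 ± 6.46 CPM, a log2 fold change of 0.63. UMPS, which makes UMP, stood at 34.6 ± 10.1 against 25.0 ± 1.28 CPM, a log2 fold change of 0.47. CTPS1, which makes CTP and is used by dividing lymphocytes, stood at 75.7 ± 7.51 against 48.9 ± 11.1 CPM and was the one gene of the list with all relapse libraries above all non-relapse libraries.

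The remaining members were smaller or opposite. CTPS2, the sister enzyme of CTPS1, had a log2 fold change of 0.41, the nucleoside diphosphate kinase NME1 0.28 and the UMP/CMP kinase CMPK1 0.10. Those values turned negative in some settings: CMPK1 gave -0.0317 with RLE factors, -0.20 with upper-quartile factors and -0.17 with total library size, and NME1 gave -0.0184 and -0.00526 with the latter pair. NME2 had a log2 fold change of -1.17 at 1.03 ± 1.00 against 2.28 ± 0.863 CPM. Without relapse replicate 2 it was at -2.41, and CTPS2 was at 1.12 without non-relapse replicate 2 and at -0.0736 without non-relapse replicate 3. NME1 and NME2 are near-identical neighbours on chromosome 17, so how reads were divided between them is uncertain.

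By edgeR's quasi-likelihood test, DHODH had an adjusted p of 0.824, which ran from 0.373 to 1 over the alternatives, with log2 fold changes from 0.26 to 1.03. Its exact two-sided permutation p was 0.2, where 0.1 is the smallest that 3 against 3 libraries can give. DESeq2 gave a log2 fold change of 0.57 and an adjusted p of 0.797. Of the 8 pyrimidine genes, 7 were higher in the relapse group, and 0 passed over all genes or when adjusted over the list alone, where the smallest adjusted p was 0.316. The median log2 fold change of the list was 0.44, at percentile 82.1 among 10000 random lists of genes with matched mean CPM. The list had an adjusted camera p of 0.152 (adjusted p = 0.664 with an estimated correlation). It passed without relapse replicate 1 (adjusted p 0.0389), without non-relapse replicate 2 (0.0267) and with no filter on low counts (0.00169), and its median relative to all genes was -0.12 with non-relapse replicates 1 and 3 left out.

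**Figure D2:**
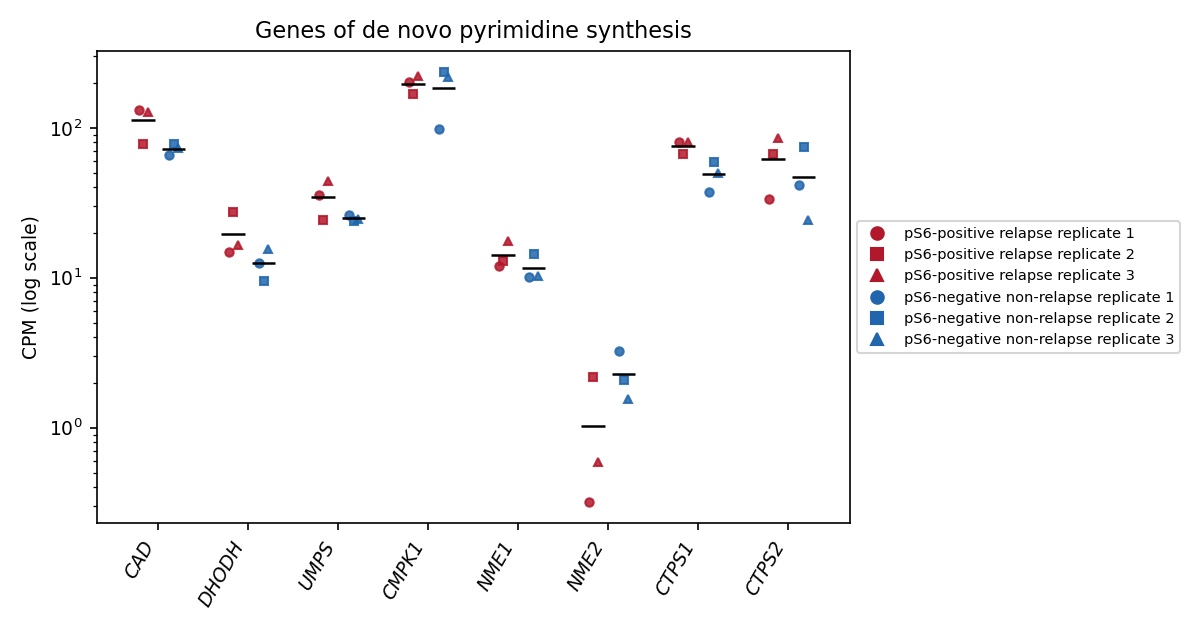
Points give the CPM of each library on a log scale for the 8 genes of de novo pyrimidine synthesis, red for pS6-positive relapse and blue for pS6-negative non-relapse, and horizontal lines give the mean of 3 libraries. DHODH libraries of the groups overlap around means of 19.6 and 12.5 CPM, and those of CTPS1 do not overlap.

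Of the genes that met the naming rule, ADD2, ABCB4 and SH3BP5 had the smallest p by edgeR, and all were low in the relapse cells. DDIT4L (chromosome 4, 100185870 to 100190782), also called REDD2, an inhibitor of mTORC1 signalling, stood at 2.89 ± 1.95 CPM (SD, n = 3) in the relapse group and 138 ± 97.2 in the non-relapse group, 48.0-fold lower. The zinc finger transcription factor gene ZNF516 (chromosome 18, 76358190 to 76495190) stood at 1.17 ± 1.41 against 57.5 ± 23.97 CPM. ABCB4 (chromosome 7, 87401697 to 87480435), a phospholipid transporter, stood at 2.12 ± 1.73 against 42.6 ± 4.78 CPM. ADD2 (chromosome 2, 70607618 to 70768225), a protein of the membrane skeleton, stood at 2.62 ± 0.229 against 29.9 ± 7.71 CPM, and SH3BP5, which binds and inhibits the B cell kinase BTK, at 77.7 ± 8.93 against 394 ± 126 CPM.

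A further 7 genes completed the 12 of smallest p in that direction. The growth factor gene PDGFA had a log2 fold change of -4.10, the endothelial surface protein gene CLEC14A -3.62, the pyrophosphate transporter gene ANKH -3.06 and the Mediator subunit gene MED12L -4.11. HDX, a homeobox gene, was at -4.27, the cadherin gene DCHS2 at -4.003 and the membrane protein gene TMEM8B at -2.35. By DESeq2 all 12 passed, with adjusted p from 4.11e-07 for ADD2 to 0.0154 for TMEM8B. By edgeR their adjusted p was 0.824 each, and with no filter on low counts 11 of them passed, TMEM8B being the exception. In every setting run the 12 kept their direction. The naming rule favours this, since it asked for no overlap between the groups. Fold sizes did move: the lowest log2 fold changes over the settings were -10.57 for HDX, -11.47 for MED12L, -10.5 for DCHS2 and -5.34 for ADD2. Single libraries moved some folds by over 1.5 times: without relapse replicate 2, log2 fold changes were -5.29 for ABCB4, -5.19 for HDX, -7.43 for ZNF516, -4.71 for PDGFA and -4.84 for DCHS2. Without non-relapse replicate 2, ZNF516 was at -5.10, PDGFA at -3.06 and DCHS2 at -3.06. Without non-relapse replicate 1, DDIT4L was at -6.23 and MED12L at -3.31, and without non-relapse replicate 3 MED12L was at -4.78.

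Among the 12 genes named as high in the relapse cells were NRN1, F2R and LCN8. NRN1 (chromosome 6, 5997999 to 6007605), a neuritin anchored on the cell surface, stood at 176 ± 242 CPM against 2.85 ± 1.29, with the SD above the mean in the relapse group. Without relapse replicate 1 its log2 fold change was 3.44, against 5.925 with all libraries, and that of F2R was 3.06 against 3.999. The thrombin receptor gene F2R (chromosome 5, 76716043 to 76735781) stood at 41.7 ± 28.4 against 2.59 ± 1.38 CPM. LCN8 (chromosome 9, 136754386 to 136758543), a lipocalin, stood at 39.0 ± 19.7 against 3.81 ± 1.08 CPM, and ANPEP, the aminopeptidase known as CD13, at 27.5 ± 3.91 against 4.58 ± 2.23 CPM. These 4 passed by DESeq2, with adjusted p of 6.85e-06, 0.000131, 0.000602 and 0.0108, and by edgeR with no filter on low counts, but not by edgeR with its filter (0.824 each).

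The other 8 of the 12 genes higher in the relapse group did not pass by edgeR with its filter or by DESeq2 on all genes. DESeq2 on the genes tested by edgeR passed all 8 (adjusted p from 0.00198 for GUSB to 0.0277 for ZNF423), and edgeR with no filter on low counts passed SH3PXD2A (0.0158). GUSB, the lysosomal beta-glucuronidase, stood at 105 ± 13.5 against 36.7 ± 7.63 CPM, and CDCA7L, a MYC-interacting protein gene, at 198 ± 39.9 against 67.3 ± 20.8 CPM. SH3PXD2A, a scaffold of invasive cell protrusions, had a log2 fold change of 2.07, the protein kinase gene PKN3 1.83 and ZNF423, a zinc finger factor that binds the B cell factor EBF1, 1.74. The peroxisomal transporter gene ABCD3 was at 1.59, the cadherin gene CELSR2 at 1.58 and the nuclear receptor coactivator gene NCOA7 at 1.36.

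By edgeR's quasi-likelihood test 0 of 21575 genes passed an adjusted p of 0.05, the smallest being 0.824. Unadjusted p was under 0.05 for 718 genes, 456 of them higher in the relapse group, where chance would give 1079. DESeq2 passed 76 genes, 12 higher and 64 lower. Of these, 73 were tested by edgeR too, all in the same direction and with an unadjusted edgeR p of at most 0.0342. In 5 of the 10 splits of the libraries, the real one among them, DESeq2 passed at least 76 genes. Limma voom passed 0 genes with and without sample weights, with 3110 and 688 at an unadjusted p under 0.05, and edgeR with no filter on low counts passed 104 (58 higher, 46 lower). Groups did not overlap for 2134 genes, 9.89% of those tested, against 10% by chance, and 1500 of them were higher in the relapse group. The share of genes of unadjusted p under 0.05 that were higher was 63.5%, with a median log2 fold change of all genes of 0.02. It was 45.9%, 25.7% and 29.1% with RLE, upper-quartile and total-count scaling, where the median moved to -0.12, -0.30 and -0.28.

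**Figure D3:**
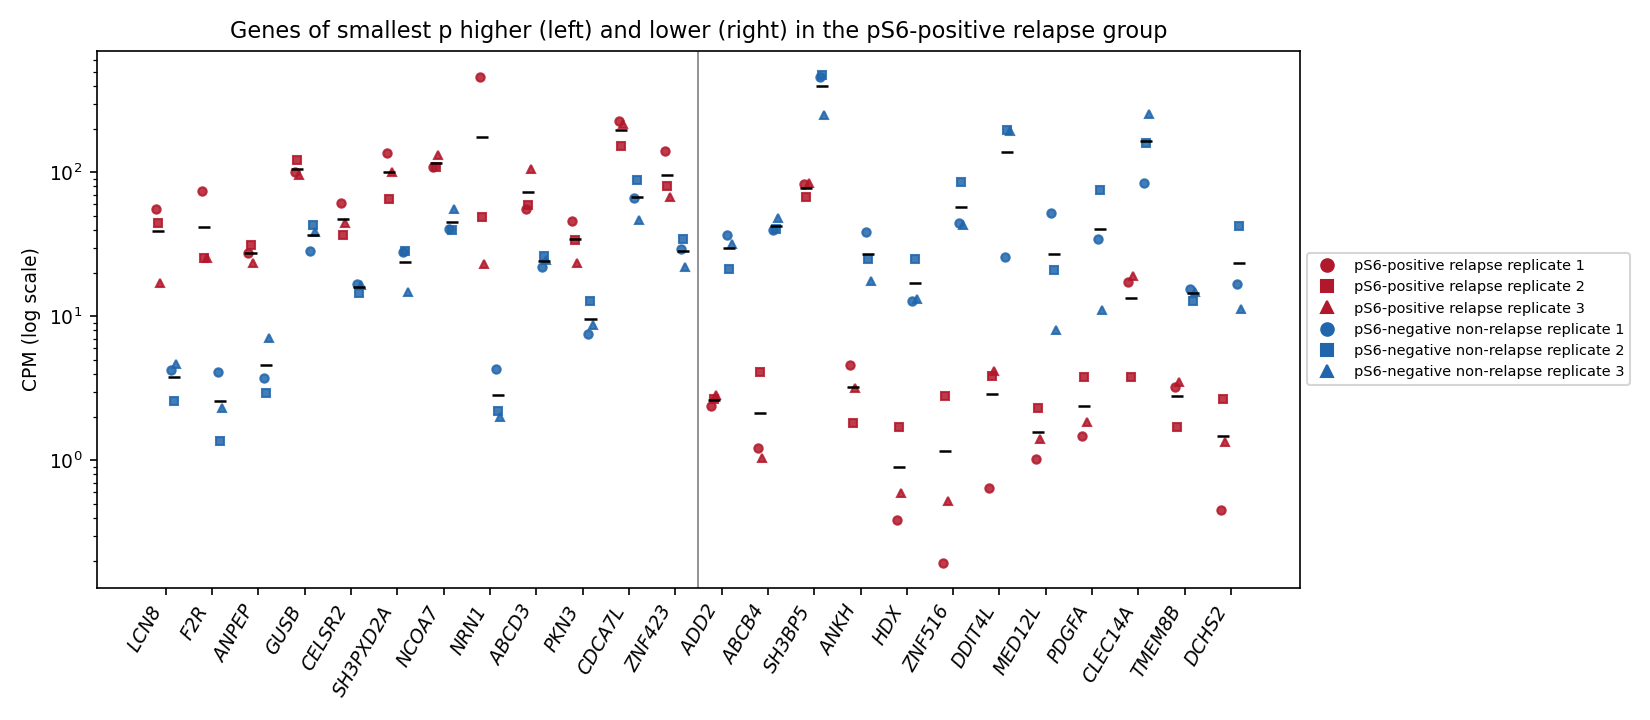
Points give the CPM of each library on a log scale for the 12 genes of smallest p higher (left) and the 12 lower (right) in the pS6-positive relapse group (red) than in the pS6-negative non-relapse group (blue), and horizontal lines give the mean of 3 libraries. By the naming rule no libraries of the groups overlap; NRN1 has the widest spread, 176 ± 242 CPM in the relapse group.

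As a group, genes of dividing cells were higher in the relapse group, though not in each of its libraries. Relapse replicate 1 stood highest for histones, DNA replication and mitosis (levels of 1.15, 0.97 and 1.998 relative to the mean of the libraries, log2). Relapse replicate 2 (-0.43, -0.55 and -0.95) lay below non-relapse replicates 1 (-0.17, -0.15 and -0.11) and 2 (-0.13, 0.06 and 0.12). Replication-dependent histone genes, which package new DNA and are used in S phase, were higher for 32 of 33 members, with a median log2 fold change of 1.01. Libraries were primed on poly(A) tails, and how far their counts follow the full amount of histone RNA was not tested. H4C4 stood at 68.9 ± 44.3 CPM (SD, n = 3) against 14.9 ± 1.53, H2BC11 at 205 ± 102 against 66.7 ± 24.4 and H2AC4 at 48.2 ± 33.1 against 14.4 ± 2.81. DNA replication genes were higher for 25 of 26 members, with a median of 0.80. Among them the replicative helicase subunits MCM2 (265 ± 90.04 against 104 ± 38.7 CPM), MCM7 (368 ± 121 against 164 ± 45.3) and MCM5 (284 ± 107 against 124 ± 39.3) had the smallest p. Mitosis genes were higher for 21 of 21, with a median of 1.17, and CDC20, the activator of the anaphase complex, stood at 37.3 ± 41.0 against 11.02 ± 3.67 CPM, CCNB2 at 48.2 ± 47.3 against 16.6 ± 8.86 and the kinase gene AURKA at 19.98 ± 20.8 against 7.07 ± 1.48. Enzymes of dNTP synthesis were higher for 8 of 9, with a median of 0.72, including DHFR, the target of methotrexate, at 106 ± 55.2 against 56.2 ± 11.98 CPM, DUT (log2 fold change 0.68) and DTYMK (0.85).

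With upper-quartile factors the medians were 0.57 for histones, 0.40 for DNA replication, 0.75 for mitosis and 0.43 for dNTP synthesis. By camera in the main test, adjusted p was 7.88e-13 for histones, 4.35e-07 for DNA replication, 0.000119 for mitosis and 0.0147 for dNTP synthesis. None of them passed when the correlation was estimated: adjusted p = 0.664 with an estimated correlation for histones, DNA replication and dNTP synthesis, and 0.688 for mitosis. Without relapse replicate 1 the mitosis list lost its call and camera's direction turned (adjusted p 0.462, median log2 fold change -0.29, against a median of -0.51 for all genes), AURKA stood at a log2 fold change of -0.0209, dNTP synthesis was at an adjusted p of 0.204, and the histone list kept its call. Without non-relapse replicate 3 mitosis (0.064) and dNTP synthesis (0.300) lost theirs, as did dNTP synthesis at a mean of at least 5 CPM (0.151). With the background subtracted, DNA replication and mitosis kept their calls and dNTP synthesis (0.176) lost its call. With the background level as a covariate, DNA replication (0.569), mitosis (0.881, direction turned) and dNTP synthesis (0.881) lost their calls. With both libraries of highest background left out, DNA replication (0.565), mitosis (0.842) and dNTP synthesis (0.923, direction turned) did. Single members moved with relapse replicate 1 as well: without it, log2 fold changes were 0.148 for CDC20 and CCNB2 (1.76 and 1.53 with all libraries), 0.25 for DHFR (0.91) and 0.16 for DTYMK (0.85). They were 1.38 for H4C4 (2.21), 1.01 for H2BC11 (1.62) and 0.84 for H2AC4 (1.74). CCNB2 was at 2.21 without non-relapse replicate 2. H4C4 passed by edgeR with no filter on low counts (adjusted p 0.0146) and by DESeq2 on the genes tested by edgeR (0.0365).

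With TMM scaling, energy and translation genes were also higher in the relapse group, by less. All 23 genes of the TCA cycle were higher, with a median log2 fold change of 0.50, IDH2 standing at 209 ± 127 against 89.1 ± 52.7 CPM, FH at 49.4 ± 14.8 against 27.2 ± 11.6 and SDHA at 226 ± 174 against 103 ± 17.5. Nuclear-encoded genes of oxidative phosphorylation, the chain to which DHODH passes electrons, were higher for 65 of 73, with a median of 0.46; UQCRH of complex III stood at 98.8 ± 19.4 against 50.7 ± 18.4 CPM and COX5A of complex IV at 36.8 ± 6.01 against 18.2 ± 7.17, while NDUFV3 of complex I had a log2 fold change of -0.68. Mitochondrially encoded genes were higher for 12 of 13, with a median of 0.67, and MT-CO1 stood at 3898 ± 569 against 2237 ± 864 CPM, with MT-CYB at a log2 fold change of 0.82 and MT-ND4 at 0.85. Glycolysis genes were higher for 18 of 21, with a median of 0.61, and lactate dehydrogenase LDHA stood at 393 ± 171 against 194 ± 39.6 CPM, LDHB at 302 ± 40.0 against 185 ± 38.6 and GPI at 116 ± 29.2 against 59.1 ± 30.9. Without relapse replicate 1, log2 fold changes were 0.11 for SDHA (1.13 with all libraries), 0.44 for IDH2 (1.23) and 0.40 for LDHA (1.02). Without non-relapse replicate 2 they were 2.04 for IDH2, 1.49 for FH (0.86) and 1.68 for GPI (0.97).

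Ribosomal protein genes were higher for 68 of 73, with a median of 0.47, among them RPL6 (1040 ± 187 against 652 ± 223 CPM), RPS7 (log2 fold change 0.69) and RPL41 (0.60). Genes of the mTORC1 and S6 kinase pathway, whose activity pS6 reports, were higher for 21 of 24, with a median of 0.34. Examples were TSC2, a brake on mTORC1, at 176 ± 28.0 against 106 ± 20.4 CPM, the translation repressor gene EIF4EBP2 at 190 ± 84.7 against 105 ± 44.1 and the S6 kinase gene RPS6KB2 at 47.1 ± 15.2 against 30.6 ± 4.24. The log2 fold change of EIF4EBP2 was 0.86, with 0.27 without relapse replicate 1 and 1.47 without non-relapse replicate 2. MYC targets were higher for 14 of 17, with a median of 0.47 and with CDK4 at 73.8 ± 25.5 against 37.1 ± 11.2 CPM, TUFM at a log2 fold change of 0.69 and RANBP1 at 0.77. De novo purine synthesis was higher for 10 of 12, with a median of 0.33, and IMPDH1, which commits IMP to guanine nucleotides, stood at 73.3 ± 19.9 against 33.1 ± 8.37 CPM, with GMPS at 0.57 and ADSS2 at 0.55. Cholesterol synthesis was higher for 14 of 20, with a median of 0.47, including squalene epoxidase SQLE (42.8 ± 12.4 against 17.1 ± 2.89 CPM), the regulator SREBF2 (127 ± 35.7 against 55.4 ± 18.3) and FDPS (91.5 ± 23.2 against 44.4 ± 12.6). The medians of these and the energy lists moved with the scaling. With upper-quartile factors the median of all genes was -0.30. The list medians were then 0.045 for mTORC1, 0.029 for purine synthesis, 0.14 for cholesterol synthesis and 0.19 for ribosomal proteins and MYC targets. They were 0.16 for oxidative phosphorylation, 0.21 for the TCA cycle and 0.33 for glycolysis and mitochondrially encoded genes. The medians with TMM were also set against 10000 random lists of genes with matched mean CPM. The mTORC1 list stood at percentile 57.4 and purine synthesis at 50.7, so their medians were like those of other genes of similar level. Ribosomal proteins stood at percentile 99.8, MYC targets at 90.8 and cholesterol synthesis at 94.4. The random lists drew genes independently, while the correlations estimated within these lists were 0.83, 0.27 and 0.13. Medians of correlated genes vary more, so these high percentiles cannot tell a group difference from correlation.

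Adjusted camera p was 1.69e-09 for ribosomal proteins, 3.42e-07 for oxidative phosphorylation, 3.37e-05 for the TCA cycle, 4.52e-05 for mitochondrially encoded genes, 0.000752 for glycolysis, 0.00815 for the mTORC1 pathway and for MYC targets, 0.0147 for cholesterol synthesis and 0.0411 for purine synthesis. These calls did not hold when the correlation was estimated: adjusted p = 0.664 with an estimated correlation for the TCA cycle, mitochondrially encoded genes, glycolysis, MYC targets and cholesterol synthesis, and 0.688 for the others. Purine synthesis lost its call in 15 of 23 settings, among them RLE (adjusted p 0.0779), upper-quartile (0.175) and total-count scaling (0.160), and without relapse replicate 1 (0.124) or 3 (0.477). At a mean of at least 5 CPM it was at 0.567, mTORC1 at 0.247, MYC targets at 0.218, cholesterol synthesis at 0.165 and glycolysis at 0.0607. Without non-relapse replicate 1, ribosomal proteins (0.898), mTORC1 (0.611), MYC targets (0.274), purine (0.191) and cholesterol synthesis (0.0771) lost their calls. Without non-relapse replicate 3 this held for mTORC1 (0.208), MYC targets (0.124), purine (0.532), cholesterol synthesis (0.121), glycolysis (0.0794) and mitochondrially encoded genes (0.0794). With both of non-relapse replicates 1 and 3 left out, medians relative to all genes turned to -0.22 for the TCA cycle, -0.32 for oxidative phosphorylation, -0.23 for ribosomal proteins, -0.30 for mTORC1, -0.0637 for MYC targets and -0.16 for purine synthesis, and glycolysis (adjusted p 0.976) and cholesterol synthesis (0.891) lost their calls. With the background level as a covariate, oxidative phosphorylation (-0.0898) and mTORC1 (-0.15) turned, and in this group only mitochondrially encoded genes kept their call. With the background subtracted the picture was different. Ribosomal proteins, the TCA cycle and oxidative phosphorylation kept their calls, while mitochondrially encoded genes (adjusted camera p 0.095) and the rest of this group lost theirs. The libraries with the lowest levels of most of these lists, non-relapse replicates 1 and 3, were those of highest background.

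The pre-BCR and NF-kB lists were higher in the relapse group, and stromal markers were lower. Pre-BCR and BCR signalling, the pathway that drives pre-B cell expansion, was higher for 15 of 18 genes, with a median log2 fold change of 0.54. Phospholipase PLCG2 stood at 368 ± 62.7 CPM (SD, n = 3) against 200 ± 65.2 and VPREB3 at 108 ± 35.9 against 62.1 ± 20.9, while the kinase gene BLK had a log2 fold change of -0.95. NF-kB response genes were higher for 12 of 16, with a median of 0.69. NFKBIA, the inhibitor that NF-kB itself induces, stood at 283 ± 55.6 against 122 ± 27.0 CPM and the chemokine gene CXCL8 at 31.6 ± 32.7 against 2.61 ± 1.97, while IL1B was opposite at 37.1 ± 24.9 against 130 ± 84.5. Within the relapse group the list's level (-0.51, 0.66 and 0.59 in replicates 1, 2 and 3, log2) ran alongside that of monocyte markers (-2.31, 1.57 and 0.83). CXCL8 stood at 1.35, 66.3 and 27.0 CPM in these libraries and the monocyte gene LYZ at 1.67, 167 and 78.7 CPM. Without relapse replicate 2 the log2 fold change of CXCL8 was 2.35, against 3.62, and without relapse replicate 3 that of IL1B was -2.49, against -1.82. Stromal and endothelial markers, which the sort should leave out, were lower in the relapse group for all 9 genes tested, with a median of -1.78. PECAM1, which some B cells also carry, stood at 48.9 ± 34.4 against 280 ± 453 CPM, and CXCL12 (1.19 ± 1.24 against 5.22 ± 4.44) and COL3A1 (0.588 ± 0.426 against 3.44 ± 3.14) were near the floor. Background was highest in the same non-relapse libraries, replicates 1 and 3, that stood highest for this list. With both left out its median relative to all genes was 1.32, and PECAM1 had a log2 fold change of 1.61 without non-relapse replicate 2.

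Adjusted camera p was 0.0137 for NF-kB, 0.0147 for stromal markers and 0.0359 for pre-BCR signalling (adjusted p = 0.664 with an estimated correlation for NF-kB and stromal markers, and 0.688 for pre-BCR signalling). Pre-BCR signalling lost its call in 14 of 23 settings, among them RLE (0.0508), upper-quartile (0.0953) and total-count scaling (0.079), voom (0.0588) and a mean of at least 5 CPM (0.512), and without relapse replicate 1 (0.103), non-relapse replicate 1 (0.611) or 3 (0.538). NF-kB lost its call with voom (0.0658), at a mean of at least 5 CPM (0.0685) and without non-relapse replicate 3 (0.121). Stromal markers lost theirs with voom (0.0588), with no filter (0.0514), and without relapse replicate 1 (0.155) or 2 (0.0524) or non-relapse replicate 1 (0.0926) or 3 (0.124). In all, 16 of 43 lists passed by camera, 15 higher and 1 lower, and 0 passed with an estimated correlation or by fry (smallest adjusted p 0.614), where 0 lists also had an unadjusted p under 0.05. Of these 16, 1 list, the histones, passed in all settings other than the estimated correlation and fry. By edgeR with its filter, 0 genes of the 16 lists passed over all genes or adjusted over the list alone. In 6 of the 10 splits of the libraries, the real one among them, camera called at least 16 lists. With the background level as a covariate, the background subtracted, or both libraries of highest background left out, which sets the relapse group against non-relapse replicate 2 alone, 6 lists (2 higher, 4 lower), 8 (6 higher, 2 lower) and 8 (4 higher, 4 lower) passed. Of the 16 lists, 2 kept their call and direction with the covariate and 6 with the background subtracted. The histone list kept both in all 3 ways, by camera with its preset correlation (adjusted p 0.0393 with the covariate and 3.58e-06 with subtraction). Over all alternatives its median relative to all genes was as low as 0.35, against 0.98 in the main test. With 1 library left out the lowest was 0.73.

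**Figure D4:**
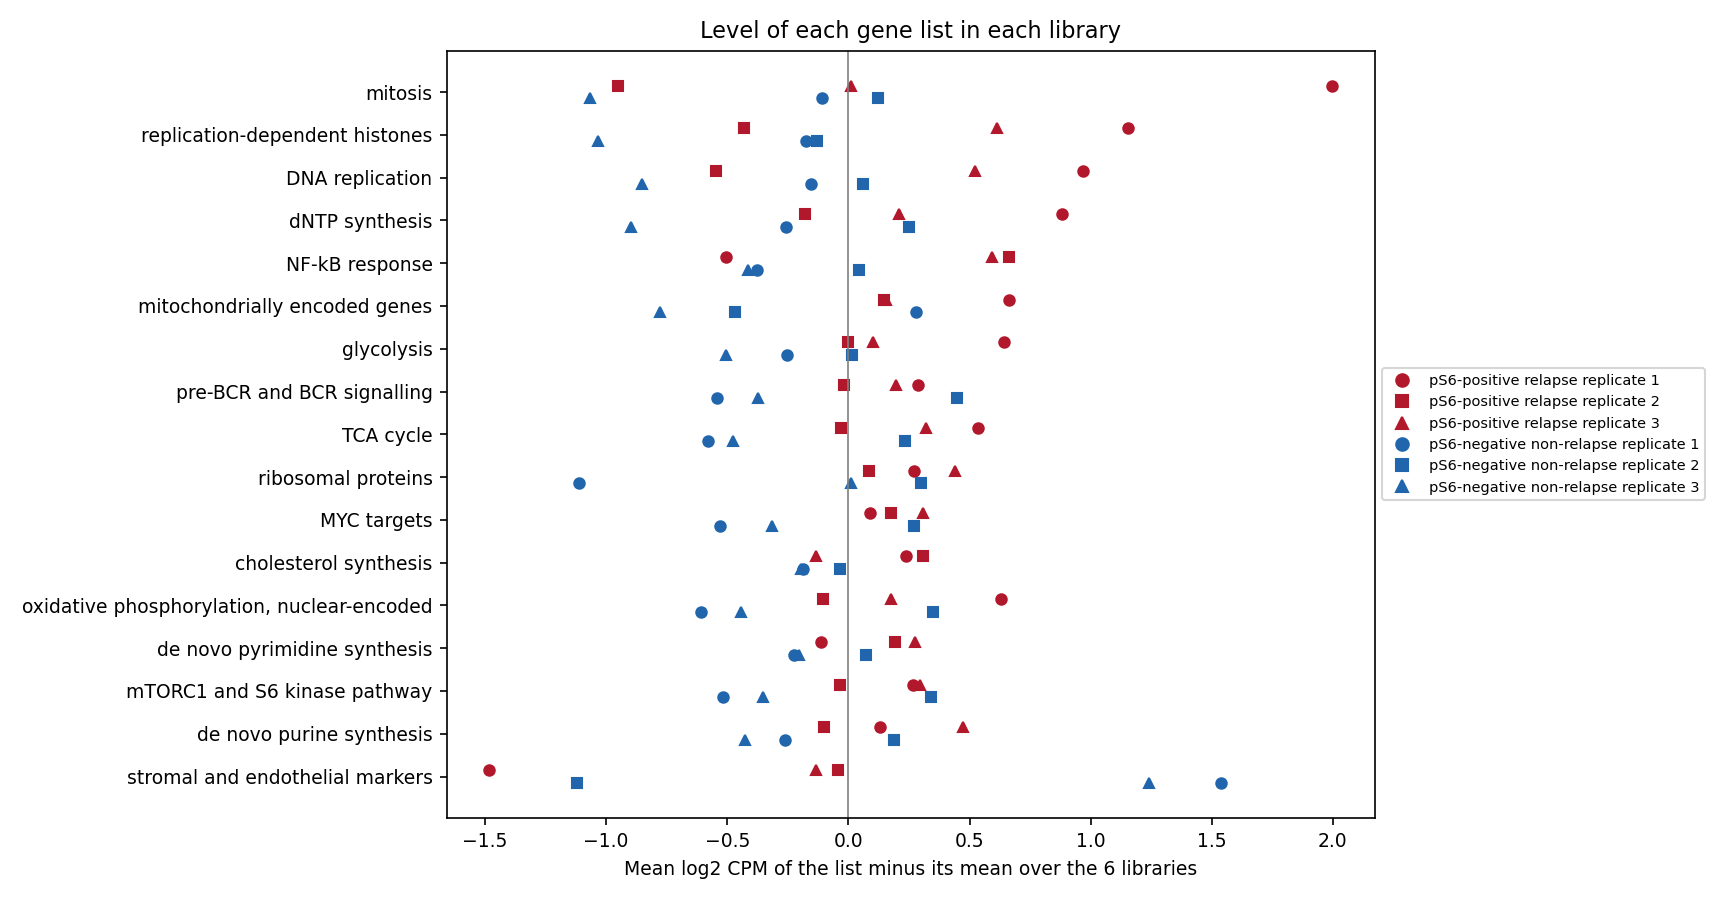
Points give, for each library, the mean log2 CPM of a list's genes minus its mean over the 6 libraries, for the 16 lists called by camera and the pyrimidine list, red for pS6-positive relapse and blue for pS6-negative non-relapse. For oxidative phosphorylation, the TCA cycle and ribosomal proteins, non-relapse replicates 1 and 3 lie below all relapse libraries and replicate 2 lies among them.

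As whole profiles, the libraries did not separate by group. The mean distance between groups was smaller than that within groups by a difference of -4.47, with an exact permutation p of 0.7 over 10 splits. Spearman correlations between libraries, across genes, ran from 0.817 to 0.910 within groups and from 0.796 to 0.923 between them.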

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

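The tests with the background as a covariate, the background subtracted, both libraries of highest background (non-relapse replicates 1 and 3) left out, protein-coding genes only, and DESeq2 on the genes tested by edgeR were chosen after the data were seen. Log2 values of lists are medians relative to all tested genes in the same setting. With 3 patients per group and a biological coefficient of variation of 0.805, edgeR recovered 28% of simulated genes at a log2 change of 2, which limits what a count of 0 can exclude. The simulation held no uneven background and no spread particular to a gene. In the real fit NRN1 (log2 fold change 5.93), ZNF516 (-5.69) and DDIT4L (-5.58) did not pass (adjusted p 0.824 each). The simulated shares therefore need not hold for these libraries. Of 98 named genes, 88 kept their direction in all settings run, which picking most of them by smallest p favours. Lists not called are given as counts: of 26 besides the pyrimidine list, 23 took the other direction in at least 1 of 23 settings and 22 were called in at least 1. Restricting values to the called lists was decided after the others were seen. Unless stated, the cause was not tested.

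The count of genes passing was 0 by edgeR (718 at an unadjusted p under 0.05), 104 with no filter on low counts, 76 by DESeq2 and 96 by DESeq2 on the genes tested by edgeR, which shared 65 genes with the 76. Of the 104 genes, 41 were shared with the DESeq2 set and 57 had no overlap between groups. The 10% given by chance holds for unselected genes and is no reference here, since the 104 were picked for the same group difference. The count of genes passing was 0 without any single library, with 6658 genes at an unadjusted p under 0.05 without non-relapse replicate 2. The DHODH log2 fold change ran from 0.26 to 0.68 with a library left out and never passed (adjusted p 0.373 to 1).

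The pyrimidine list stood at 1.58 with no filter (adjusted p 0.00169), where the median of all genes moved to -0.95, and at -0.12 (adjusted p 0.923) with both libraries of highest background left out. It ran from 0.40 to 0.87 with 1 library left out, passing at 0.79 without relapse replicate 1 and at 0.85 without non-relapse replicate 2; adjusted p over the alternatives ran from 0.00169 to 0.923. Lists passing numbered 16, against 30 with no filter, 10 at a mean of at least 5 CPM, 6 with the background as a covariate, 8 with it subtracted, 8 with both libraries left out, and 0 with an estimated correlation or fry. The range with 1 library left out was 8 (without non-relapse replicate 3) to 27 (without non-relapse replicate 2), with 10 without non-relapse replicate 1. The separation by group ran from -9.35 to 0.14 with 1 library left out, the positive value without relapse replicate 2.

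With both libraries of highest background left out, which leaves 1 non-relapse library assumed to vary like the rest, relative medians took the other sign for dNTP synthesis (-0.0494), purine synthesis (-0.16), mTORC1 (-0.30), ribosomal proteins (-0.23), MYC targets (-0.0637), TCA cycle (-0.22), oxidative phosphorylation (-0.32), pre-BCR (-0.31), NF-kB (-0.0377) and stromal markers (1.32). With the background as a covariate this held for mTORC1 (-0.15), oxidative phosphorylation (-0.0898) and pre-BCR (-0.10). For the mitosis list, camera's direction turned while the relative median stayed positive, at 0.11 with the covariate and 0.22 without relapse replicate 1 (range 0.22 to 2.15 with 1 library left out).

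Among genes, CMPK1 stood at -0.0317 with RLE, -0.20 with upper-quartile, -0.17 with total-count scaling and -0.15 at a mean of at least 5 CPM. It was at -0.17 with the covariate, -0.19 with background subtracted, -0.28 with both libraries left out, -0.0314 by DESeq2 on edgeR's genes, and from -0.35 to 0.52 with 1 library left out. NME1 stood at -0.0184 with upper-quartile and -0.00526 with total-count scaling, -0.0589 with both left out and from -0.0339 to 0.69 with 1 left out. CTPS2 stood at -0.28 with both left out and from -0.0736 to 1.12 with 1 left out. PECAM1 stood at 1.56 by voom with sample weights and from -3.22 to 1.61 with 1 left out, the top value without non-relapse replicate 2. CXCL12 stood at 0.12 with the covariate and 1.57 with both left out, COL3A1 at 1.37 and 5.95, and BCL6 at 0.19 with both left out. SDC1 stood at -1.34 by voom with sample weights and from -2.22 to 3.74 with 1 left out, PRDM1 from -0.25 to 1.46 and AURKA from -0.0209 to 1.91, in each case lowest without relapse replicate 1.

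With the replicate block, 0 genes passed, DHODH stood at a log2 fold change of 0.62 (adjusted p 0.984), PECAM1 at 0.18, the pyrimidine list at an adjusted p of 0.165, and 17 lists passed, purine synthesis not among them (0.068). The replicate numbers do not pair the patients: correlations of deviations across genes for equal numbers were -0.358, -0.574 and 0.0279.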

Other observations

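The tests of library depth, of the lists under 3 ways of handling the background and of the DESeq2 genes were chosen after the result was seen. For correlated genes, the estimated correlation and fry were fixed in advance and what they would have to show was set afterwards. Also chosen after the values were seen were the lists described by their members here. RAG1, the recombinase that rearranges immunoglobulin genes, stood at 2164 ± 2011 CPM (SD, n = 3) in the relapse group and 202 ± 120 in the non-relapse group, with no overlap, and passed by DESeq2 (adjusted p 0.0221) and by edgeR with no filter on low counts (4.49e-08) but not by edgeR with its filter (0.824); without relapse replicate 1 its log2 fold change was 2.19, against 3.42. PAX5, the factor that holds B cell identity, stood at 761 ± 371 against 358 ± 79.1 CPM, and BCL6, a repressor of pre-B and germinal centre cells, at 15.4 ± 5.42 against 30.8 ± 16.6. Without relapse replicate 1 the log2 fold change of PAX5 was 0.44, against 1.09. The list of B-lineage factors had a median log2 fold change of 0.19 and an adjusted camera p of 0.313. JCHAIN, which joins secreted antibody units, stood at 36.4 ± 26.9 against 2.02 ± 1.17 CPM; it passed by DESeq2 (adjusted p 0.00218) and by edgeR with no filter (4.15e-06), had a log2 fold change of 3.54 without relapse replicate 1, against 4.15, and was the 1 gene that passed in edgeR with its filter when adjusted over the list alone, while the folds of SDC1 and PRDM1 turned without that library (-2.22 and -0.25) and their levels, SDC1 (13.96 ± 23.4 against 1.75 ± 1.45) and PRDM1 (17.3 ± 16.2 against 8.36 ± 1.97), overlapped. The plasma cell list itself had a median of 0.26 (adjusted p 0.195). Sort markers had a median of 0.54 (adjusted p 0.193) and mature B cell markers 0.69 (0.307).

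Lists of stress, feedback and monocyte genes did not pass. The p53 list had a median log2 fold change of 0.29 (adjusted p 0.242), with SESN1, which restrains mTORC1, at 137 ± 82.5 against 38.1 ± 4.65 CPM, DDB2 at a log2 fold change of 0.61 and ZMAT3 at 1.63. In RAS-ERK feedback (median -0.18, adjusted p 0.101), CCND1 stood at 2.33 ± 1.64 against 14.8 ± 9.82 CPM and the phosphatase gene DUSP5 at 18.0 ± 12.4 against 66.5 ± 30.0, while PHLDA1 was at a log2 fold change of 2.07. In serine and one-carbon metabolism (0.28, adjusted p 0.615), SHMT2 stood at 69.6 ± 14.4 against 37.1 ± 8.74 CPM and PHGDH at 11.1 ± 5.72 against 31.2 ± 24.7, with ALDH1L2 at -0.98. Single libraries moved some of these values: PHGDH had a log2 fold change of -0.41 without non-relapse replicate 2 (-1.49 with all libraries), ALDH1L2 -1.62 without relapse replicate 1, and without relapse replicate 3 PHLDA1 was at 0.75 (2.07), SESN1 at 1.25 (1.84), ZMAT3 at 0.93, CCND1 at -3.47 (-2.66) and DUSP5 at -2.53 (-1.88). Monocyte markers had a median of 0.08 and a mean of 0.61 (adjusted p 0.8), with lysozyme LYZ at 82.4 ± 82.6 against 6.47 ± 2.33 CPM, S100A8 at 14.6 ± 13.3 against 0.652 ± 0.875 and S100A9 at 28.7 ± 24.9 against 3.43 ± 3.81, each overlapping between the groups. Without relapse replicate 2 LYZ had a log2 fold change of 2.51 (3.68 with all libraries), without relapse replicate 3 S100A8 was at 3.48 (4.41) and S100A9 at 2.44 (3.04), S100A8 was at 6.65 without non-relapse replicate 1, and S100A9 at 4.73 and ZMAT3 at 2.29 without non-relapse replicate 2. With no filter on low counts, edgeR passed LYZ (adjusted p 0.000299), S100A8 (0.00259), SESN1 (0.0471) and, of the NF-kB list, CXCL8 (0.000242).

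Other lists did not pass by camera. Median log2 fold changes were 0.42 for pyrimidine salvage, 0.26 for ribosome biogenesis, 0.35 for immediate early genes, 0.17 for MHC class II, 0.19 for the BCL2 family and 0.25 for JAK-STAT signalling. They were -0.03 for the ATF4 response, -0.24 for heat shock proteins, -0.26 for the interferon response and -0.40 for the glucocorticoid response. With the background as a covariate, 4 lists passed as lower in the relapse group by camera with its preset correlation. Among them were the interferon (adjusted p 0.000171), unfolded protein and B-lineage lists. Without the covariate these 3 did not pass, with an adjusted camera p of 0.461, 0.942 and 0.313 at the same preset correlation. With an estimated correlation it was 0.925, 0.981 and 0.8002. The interferon list stood apart in 1 non-relapse library, replicate 2 (level 1.39, against -1.44 and 0.26 in replicates 1 and 3). Among markers of other cells they were -1.10 for haematopoietic progenitors, -1.50 for T cells, -0.49 for NK cells, -1.01 for megakaryocytes, -0.89 for plasmacytoid dendritic cells and 0.08 for erythroid cells. The unfolded protein response had a median of -0.01 with a camera direction of higher, and granulocyte markers a median of 0.48 and a mean of 0.20 with a camera direction of lower.

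Background in genes that blood cells hardly use ran from 76.3 to 951 CPM across the libraries. Depth is argued against, since the share of these genes with a count still differed by 80.3 percentage points after thinning to the shallowest library. RNA of many other marrow cell types at once is argued against too. In non-relapse replicate 1 the median rate per kb of 91 markers of other marrow cells was 1.57 times that of these genes. It was 1.60 times in non-relapse replicate 3 and 2.48 times in relapse replicate 2. The markers were pooled over cell types, so this median cannot weigh RNA of a single type. Sequence spread over the genome, such as genomic DNA carried into the amplification, is a candidate source: counts and exon length had a Spearman correlation across these genes, which are not independent replicates, of 0.684 in non-relapse replicate 1, 0.609 in non-relapse replicate 3 and 0.524 in relapse replicate 2. It stays open, as does a difference in sample handling (the labels give no batch). Against it, the correlation was also 0.557 in relapse replicate 3, a library of lower background (0.378 and 0.163 in the remaining ones). Counts per exon length were not fully even in the libraries of highest background either. Chi-square per degree of freedom was 17.4 in non-relapse replicate 1, 4.38 in non-relapse replicate 3 and 11.03 in relapse replicate 2. These libraries were nonetheless less uneven than the others, which goes with this candidate. The others stood at 99.93 in relapse replicate 1, 69.19 in relapse replicate 3 and 160 in non-relapse replicate 2.

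Gene lists were called for 16 of 43, and 15 of these lost the call or its direction in at least 1 of 3 ways of handling the background. Uneven background may thus take part in them. A lost call was not always a smaller difference. With the background subtracted, stromal markers lost theirs (adjusted camera p 0.095) at a median log2 fold change of -2.23, against -1.78 in the main test. The histone list was the 1 list that kept its call in all 3, by camera with its preset correlation. The correlation estimated for this list was 0.70, and with it the list did not pass (adjusted camera p 0.664). Its calls therefore cannot decide whether background alone gave the difference, which stays open for this list too. Correlated genes within the lists cannot be told apart from a group difference, since 0 lists passed with an estimated correlation or fry and 3 libraries per group leave that correlation poorly known. The 10 splits of the libraries are too few for a share under 0.05. The real split called 16 lists and the others 10 to 23, with 6 of the 10 splits calling at least 16. A count of 16 therefore did not set the real grouping apart. For the pyrimidine list the unadjusted camera p was 0.0673, against a smallest other of 0.023. In 2 of the 10 splits it was as small. A biological difference between patients, such as leukemia subtype, which the labels do not give, was not tested.

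Genes lower in the relapse group by DESeq2 numbered 64. In 61 of them non-relapse replicate 2, a library of low background, also stood above all 3 relapse libraries. In those 61 the difference thus did not rest on non-relapse replicates 1 and 3 alone. The count cannot weigh uneven background as a source of the set, because DESeq2 picked the genes for this same group difference. Groups did not overlap for 58 of the 64. Splits are too few here as well. The edgeR test passed 0 genes in the real split and at most 2553 in another, with 10 of the 10 splits giving as many. DESeq2 passed 76 and at most 9782, with 5 of the 10 splits giving as many. A DESeq2 count of 76 therefore did not set the real grouping apart either. The split with 2553 and 9782 put relapse replicate 2 with non-relapse replicates 1 and 3, the 3 libraries of highest background, which points to a structure of the samples. Whether pS6, relapse or another difference between the patients goes with the 64 genes stays open and may need more donors; DESeq2 on the genes tested by edgeR passed 96 genes, 65 of them shared.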
